A study of Homo sapiens with 41 samples.

How the data were processed

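RNA of WI38hTERT cells, human embryonic lung fibroblasts that carry telomerase, was measured on 41 Illumina expression beadchip arrays. Per the labels, the cells held a doxycycline-induced hairpin against H2AFJ or a non-targeting hairpin, and senescence was induced with etoposide, a topoisomerase II inhibitor that breaks DNA. Per the labels' protocols, total RNA was amplified and hybridised as biotinylated cRNA.

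The deposited values are probe intensities on a linear scale, which the authors made with GenomeStudio per the submitters' processing notes, with no version given. Sorted values agreed across all 41 arrays with a spread of at most 0.28% at any rank and the array medians lay between 124.1 and 124.2, so the deposited intensities had been quantile normalized over all arrays together. Values ran from 91.4 to 29764. Whether the authors corrected the background is not given in the sources used here. A further deposited table of non-normalized signal and detection p-values names its columns only by a running number that matches no label, so it was inspected and is not used here. The test planned before the data were examined, which started from that table, was replaced by the same model on log2 of the deposited normalized intensities.

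Probes were named through the platform annotation. Of 47307 probes, 30106 had 1 gene symbol, 8 had several and were left unnamed, and 17193 had none in that annotation. The Entrez gene number of 30067 probes matched the reference table of current symbols. H2AFJ is named H2AJ there. The planned filter on detection p-values could not be run without the other table. In its place, chosen after the data were examined, the 95th percentile of 437 olfactory receptor probes, genes not expected in fibroblasts, served as the background level of each array, which lay between 129.2 and 135.8. Between 17035 and 19933 probes per array lay above it. Probes above it on at least 3 arrays were kept, and the probe with the highest mean stood for each gene, which left 13953 genes.

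Groups came from the sample labels alone, with 9 groups in 2 sets of 18 and 23 arrays. Group means were fitted over all 41 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as changed. Fold changes are given on the log2 scale with their standard error (SE) from this fit, and group means with the SD over arrays. A total of 21 gene lists, fixed before the data were examined, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists of a comparison. The estimated correlation between members, taken within the labelled groups, reached 0.956 for mitosis genes, far above the preset value. For lists with so high a correlation the preset p-values and the counts of members with the same sign count shared variation many times. Arrays of unlike state under 1 label would raise the estimate. A list that did not pass with it is therefore not shown to be unchanged. The median, the mean and the direction camera gave differed in sign only for lists with an adjusted p of at least 0.3549 at the preset correlation. The code was tested on simulated arrays with 200 changed genes. With each gene's own SD within the labelled groups, 92% of 4-fold and 70% of 2-fold changes among 13953 genes were recovered for the control senescence comparison, and 91% and 68% for the hairpin 3 comparison in senescence. The simulated changes lay only in brighter genes, with right labels and noise independent between genes. These shares therefore do not give the power of the real comparisons. The median SD within labels was 0.189 on the log2 scale, against 1.38 for H2AJ and 2.57 for CXCL8 on senescent controls of set 1.

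The rule for named genes was fixed beforehand. It took H2AFJ in every comparison, the 8 largest changes in each direction among changed genes (leaving out provisional and open reading frame symbols), up to 4 members of each list described, and a fixed set of senescence and secretome genes. No gene passed the threshold, so no gene was named as a largest change. The 6 lists described by their members in every comparison (mitosis, interferon-stimulated, cytokine and chemokine, cholesterol synthesis, p53 target and extracellular matrix genes) were picked after their tests had been seen. CSF2 had no named probe in the annotation and is not analysed here. TOP2A and GDF15 were added to the genes followed on single arrays after their values had been seen.

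Alternatives were normexp background correction of the normalized intensities with an offset of 50, no filter on dim probes, a stricter filter (the 99th percentile on at least 5 arrays), only the arrays compared, each set fitted on its own, a trended and robust prior, array weights, the mean of all probes of a gene, stricter thresholds, a replicate block where numbers were shared, and leaving out each array in turn. A term for the position of an array in the deposited table, and the last 18 arrays alone, were added after the data were examined. The number of arrays limits the precision of each mean. The labels do not say that arrays of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used for preparation and plots.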

Results

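Gene expression was measured on 41 arrays of WI38hTERT fibroblasts, grouped by their labels into 9 groups. In set 1 these were 4 arrays of proliferating and 5 of senescent cells with the non-targeting hairpin (controls), and 5 proliferating and 4 senescent arrays with hairpin 2 against H2AFJ, which encodes the histone variant H2A.J. Set 2 held 3 arrays of senescent controls, 5 proliferating and 5 senescent arrays of hairpin 2 cells complemented with H2A.J, and 5 proliferating and 5 senescent arrays with hairpin 3. For set 1 the labels gave 4 days of doxycycline beforehand (4 with no unit on 4 senescent controls), and for senescence 2 weeks of etoposide followed by 1 week without it. No pair of arrays held identical values, and the highest correlation between any pair was 0.9961. Between 17035 and 19933 of 47307 probes lay above background on each array.

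H2AJ, the current symbol of H2AFJ on chromosome 12, had 1 probe (ILMN_1708728), which lay above background on all 41 arrays. Its intensity ran from 165 to 3906 over the arrays, a 23.6-fold range, and this range did not follow the labels. Arrays labelled as controls in set 1 ran from 1798 to 2843 in proliferation (log2 mean 11.01 ± 0.31, SD, n = 4) and from 301 to 3009 in senescence (10.49 ± 1.38, SD, n = 5). Arrays labelled hairpin 2 ran from 165 to 2265 in proliferation (9.56 ± 1.71, SD, n = 5) and from 260 to 1768 in senescence (10.03 ± 1.34, SD, n = 4). In set 2, H2AJ lay between 324 and 3906 on arrays labelled senescent controls (n = 3). It lay between 310 and 3608 on those labelled hairpin 3 in proliferation (n = 5) and between 496 and 2421 on those labelled hairpin 3 in senescence (n = 5). On complemented arrays it lay between 434 and 1831 in those labelled proliferating and between 1316 and 3834 in those labelled senescent (n = 5 each). A construct that restores H2A.J may lack the part the probe reads, so H2AJ is a weaker check of the labels on complemented arrays. Because the targeted gene goes against the labels on many arrays, all groups here are those of the labels. Every direction is that of arrays labelled so, and was not shown to be that of the cells the labels name.

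**Figure D1:**
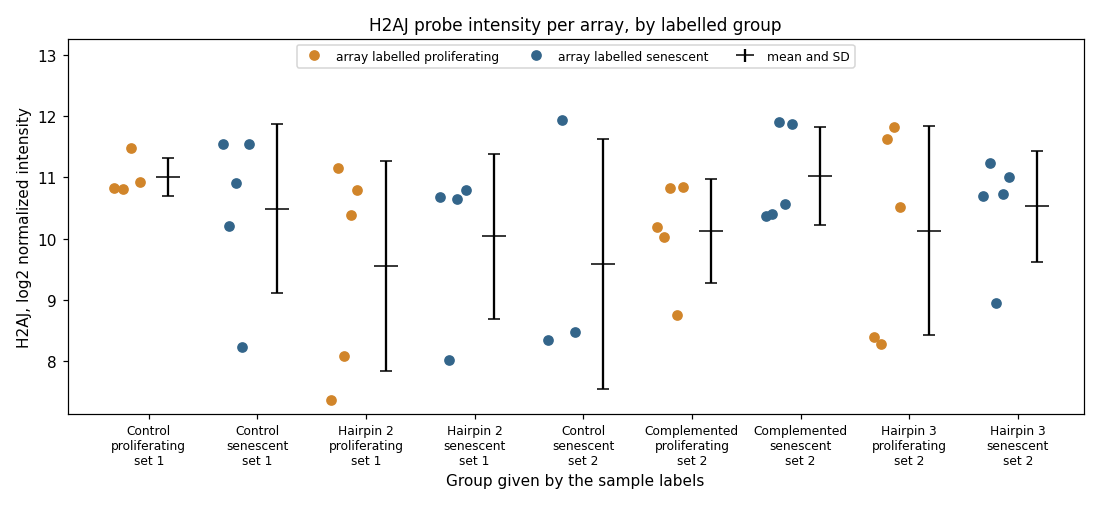
H2AJ log2 normalized intensity (y axis) on each of the 41 arrays, by the group its label gives (x axis). Points are arrays, orange for those labelled proliferating and blue for those labelled senescent, and the bars give mean and SD; arrays of 1 labelled group lie up to 13.7-fold apart, from 165 to 2265 in linear intensity for those labelled hairpin 2 in proliferation.

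The senescence comparison of controls asked what etoposide-induced senescence changed in cells with the non-targeting hairpin. Of 13953 genes 0 passed (limma, 406 at an unadjusted p under 0.05 against 698 expected by chance), and the senescence markers did not pass. Such counts lay below 698 in every comparison (160 to 578) except that of the senescent controls of both sets. Under these labels 698 is therefore a poor reference, and a low count does not show that nothing changed. CDKN1A, the p53-induced cell cycle inhibitor p21, averaged 14.01 ± 0.88 (SD, n = 5) on arrays labelled senescent and 14.41 ± 0.53 (SD, n = 4) on those labelled proliferating (limma adjusted p = 0.9993, as for every gene named in this comparison). Its intensity reached 27407 on these arrays, near the highest value of the table (29764), so a rise above that level is not well measured. CDKN2A, which encodes p16, differed by -0.31 ± 0.29 (SE) and H2AJ by -0.52 ± 0.84. The proliferation marker MKI67 was not above background on any of these arrays, and the nuclear lamina gene LMNB1 was above it on 2 of 5 arrays labelled senescent and 1 of 4 labelled proliferating, so no difference is given for them. The inflammatory cytokine genes IL6 and CXCL8 differed by -0.87 ± 0.82 and -1.57 ± 1.36.

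All 36 mitosis genes had a positive difference on arrays labelled senescent, with a median of 0.47, among them PRC1 at 0.93 ± 1.00 (SE) and the topoisomerase TOP2A at 0.75 ± 1.11. Of 37 interferon-stimulated genes 33 had a negative difference (median -0.45), among them MX1 at -1.46 ± 0.98 and OAS2 at -1.12 ± 0.77. Of the 21 lists 8 passed with the preset correlation, 4 toward higher and 4 toward lower values. They included mitosis genes (adjusted p = 0.00031), interferon-stimulated genes (adjusted p = 0.000182) and the 20 cholesterol synthesis genes (adjusted p = 0.00365, median 0.14, with ACAT2 at 0.58 ± 0.47). No list passed with an estimated correlation or with fry, and with the former the adjusted p was 0.81 for mitosis and interferon-stimulated genes and 0.416 for cholesterol synthesis genes. Of 25 cytokine and chemokine genes 18 had a negative difference (adjusted p = 0.105), with IL1A at -1.24 ± 0.86 and IL1B at -1.23 ± 0.76, each above background on 4 of 5 arrays labelled senescent. No list member passed, adjusted over the list alone or over all genes. Without replicate X of the senescent controls the H2AJ difference turned to 0.04 and 0 lists passed.

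**Figure D2:**
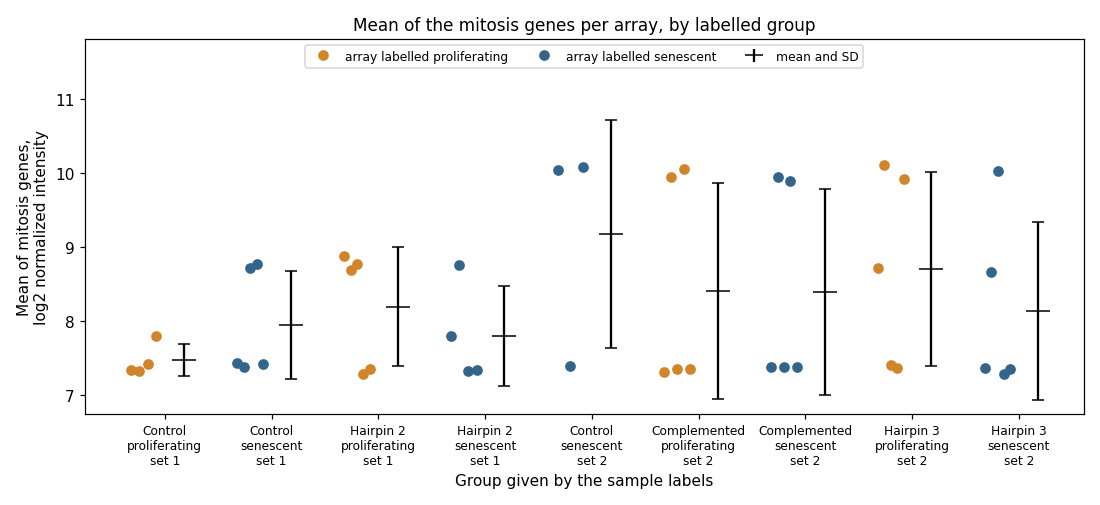
Mean log2 normalized intensity of the 36 mitosis genes (y axis) on each array, by the group its label gives (x axis). Points are arrays, orange for those labelled proliferating and blue for those labelled senescent, with mean and SD as bars; arrays at the low and the high end occur under both labels, with group means between 7.47 and 9.17.

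Hairpin 2 in senescence asked what H2AFJ depletion changed in senescent cells of set 1. H2AJ averaged 10.03 ± 1.34 (SD, n = 4) on arrays labelled hairpin 2 and 10.49 ± 1.38 (SD, n = 5) on controls, a difference of -0.45 ± 0.84 (SE) that did not pass (limma adjusted p = 0.9999) and that turned to 0.22 without replicate P of hairpin 2. Genes of the senescence secretome did not pass either (limma adjusted p = 0.9999 for each). The differences were 0.19 ± 0.86 for IL1A, 0.33 ± 0.76 for IL1B, -0.32 ± 0.82 for IL6, -0.36 ± 1.36 for CXCL8, -0.58 ± 1.49 for CXCL1, -0.56 ± 0.92 for CCL2 and -0.46 ± 0.50 for the collagenase gene MMP1. No gene of 13953 passed (limma, 195 at an unadjusted p under 0.05), and no list of 21 passed. Without replicate P of hairpin 2 or replicate X of the controls, 8 and 7 lists passed with the preset correlation. Of 25 cytokine and chemokine genes 16 had a negative difference (adjusted p = 0.346 with the preset correlation), and of 37 interferon-stimulated genes 22 did (adjusted p = 0.436).

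In proliferation, H2AJ averaged 9.56 ± 1.71 (SD, n = 5) on arrays labelled hairpin 2 and 11.01 ± 0.31 (SD, n = 4) on controls, a difference of -1.45 ± 0.84 (SE) with a limma adjusted p of 0.9614, which every gene named here shared. Without replicate H of hairpin 2 it was -0.91. All 37 interferon-stimulated genes had a negative difference (median -0.61), with MX1 at -2.12 ± 0.98, IFI27 at -1.97 ± 0.94 and ISG15 at -1.51 ± 0.67. Of 25 cytokine and chemokine genes 22 did (median -0.27), with CXCL8 at -2.86 ± 1.36, CXCL1 at -1.92 ± 1.49 and IL6 at -1.74 ± 0.82. CXCL8 reached 28129 on the controls, near the highest value of the table (29764). CXCL1 was above background on 4 of 5 arrays labelled hairpin 2, so neither difference is well measured. All 36 mitosis genes had a positive difference (median 0.66), with PRC1 at 1.51 ± 1.00. The extracellular matrix genes FBN2 and COL12A1 differed by 0.95 ± 0.38 and 0.88 ± 0.38, and the cholesterol synthesis genes INSIG1 and HMGCS1 by 0.92 ± 0.57 and 0.45 ± 0.18. Not 1 of 13953 genes passed (limma, 578 at an unadjusted p under 0.05). With the preset correlation 14 lists passed, 5 toward higher and 9 toward lower values, and without replicate I of hairpin 2 the count fell to 9. Among them were interferon-stimulated genes (adjusted p = 1.83e-10), cytokines and chemokines (adjusted p = 0.000145) and mitosis genes (adjusted p = 1.56e-06). With an estimated correlation no list passed (adjusted p = 0.458 for these 3). A single member, of the leukocyte markers, passed when adjusted over the list alone.

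The interaction asked whether hairpin 2 acted differently in the senescent and the proliferating state. H2AJ gave 1.00 ± 1.19 (SE), IL1A 1.53 ± 1.22, IL6 1.42 ± 1.16 and CXCL8 2.50 ± 1.93 (limma adjusted p = 0.9998 for each). Of 37 interferon-stimulated genes 35 had a positive interaction (median 0.73, MX1 at 1.89 ± 1.39), and 36 of 36 mitosis genes a negative one (median -0.84, TOP2A at -1.43 ± 1.58). The interaction passed for 0 genes (limma, 455 at an unadjusted p under 0.05) and, with the preset correlation, for 9 lists. It passed for no list with an estimated correlation, where the lowest adjusted p was 0.2718.

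Hairpin 3 in senescence asked the depletion question with another hairpin in set 2. H2AJ averaged 10.52 ± 0.91 (SD, n = 5) on arrays labelled hairpin 3 and 9.59 ± 2.03 (SD, n = 3) on senescent controls, a difference of 0.94 ± 0.92 (SE) in the direction opposite to depletion (limma adjusted p = 0.8595). It was 2.11 without replicate 8 of the controls, and 0.32 and 0.39 without replicates 9 and 7. All 36 mitosis genes had a negative difference (median -1.04), with CDC20, an activator of the anaphase-promoting complex, at -2.07 ± 1.60. All 37 interferon-stimulated genes had a positive one (median 0.40), with IFI27 at 1.40 ± 1.03 and IFI6 at 1.21 ± 0.70. IL1A differed by 1.01 ± 0.94, IL1B by -0.29 ± 0.83, IL6 by 0.12 ± 0.90, CXCL8 by 0.07 ± 1.48 and CCL2 by 0.61 ± 1.00. Of 25 p53 targets 22 had a positive difference (median 0.23), with GADD45A at 0.91 ± 0.50 and CDKN1A at 0.68 ± 0.70, and the sterol methyl oxidase gene MSMO1 differed by 1.01 ± 0.35. Again 0 of 13953 genes passed (limma, 447 at an unadjusted p under 0.05). With the preset correlation 8 lists passed, and 3 without replicate 7 of the controls. The 8 included mitosis (adjusted p = 5.7e-09), interferon-stimulated (adjusted p = 0.000165) and p53 target genes (adjusted p = 0.000379). No list passed with an estimated correlation (adjusted p = 0.7472 for each of these). With array weights 3127 genes passed and H2AJ differed by 2.01 (limma adjusted p = 0.0301), away from the direction of depletion. The weights were 3.474, 2.314 and 0.413 for controls 7, 9 and 8, so control 8 counted little, and H2AJ came near its difference without that array. Under the other alternatives the limma adjusted p of H2AJ lay between 0.4176 and 1. With 0 genes passing in either hairpin comparison in senescence, none could be shared. The fold changes of hairpins 2 and 3 correlated at r = -0.07 (Spearman's rho = -0.09) across genes, which are not independent replicates. Both are contrasts of labels, so this value does not show whether the 2 hairpins act alike.

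Complementation asked whether H2A.J supplied to hairpin 2 cells brought senescent cells back to controls. H2AJ averaged 11.02 ± 0.79 (SD, n = 5) on complemented arrays labelled senescent against 9.59 ± 2.03 (SD, n = 3) on controls, a difference of 1.43 ± 0.92 (SE) that did not pass (limma adjusted p = 0.9996). It was 2.61 without replicate 8 of the controls, and 0.81 and 0.88 without replicates 9 and 7. The probe may not read the supplied H2A.J, so H2AJ need not measure complementation here or in the comparison that follows. CXCL8 differed by -0.72 ± 1.48, IL1B by -0.89 ± 0.83, IL6 by -0.44 ± 0.90 and CXCL1 by 0.21 ± 1.62, and 36 of 36 mitosis genes had a negative difference (median -0.79, CDC20 at -1.55 ± 1.60). The count of genes that passed was 0 of 13953 (limma, 184 at an unadjusted p under 0.05). With the preset correlation 5 lists passed, including mitosis genes (adjusted p = 8.19e-08) and the 25 lysosome genes (adjusted p = 0.00275, median 0.20). No list passed with an estimated correlation (adjusted p = 0.9296 for both), and 0 passed at the preset one without replicate 7 or 9 of the controls.

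The difference between the complemented and the uncomplemented hairpin 2 effect was 1.89 ± 1.25 (SE) for H2AJ, 1.09 ± 1.36 for CCL2, -0.12 ± 1.22 for IL6 and -0.36 ± 2.01 for CXCL8 (limma adjusted p = 1 for each). It passed for 0 of 13953 genes (limma, 206 at an unadjusted p under 0.05), for 5 lists with the preset correlation and for no list with an estimated one (adjusted p = 0.857 for every list). With the preset correlation 0 lists passed without control 7 or 9 or complemented 2, 3 or 5 and at an adjusted p under 0.01, and 9 passed without control X. Set against the complemented arrays, those labelled hairpin 3 in senescence differed by -0.50 ± 0.79 in H2AJ (n = 5 each). In that comparison 37 of 37 interferon-stimulated genes had a positive difference (median 0.42, adjusted p = 3.87e-07 with the preset and 0.7192 with an estimated correlation), with IFI27 at 1.00 ± 0.89 and MX1 at 0.89 ± 0.92. IL1A differed by 0.98 ± 0.81, IL6 by 0.56 ± 0.78 and the thrombospondin gene THBS2 by 0.76 ± 0.39. There 0 of 13953 genes passed (limma, 274 at an unadjusted p under 0.05).

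The senescence response was also compared within the cells carrying each hairpin. With hairpin 2, H2AJ differed by 0.48 ± 0.84 (SE) between arrays labelled senescent (n = 4) and proliferating (n = 5), IL6 by 0.56 ± 0.82, TOP2A by -0.69 ± 1.11 and the collagen gene COL3A1 by -0.57 ± 0.31. Of 29 extracellular matrix genes 26 had a negative difference (median -0.26, adjusted p = 2.96e-05 with the preset and 0.5082 with an estimated correlation), and 36 of 36 mitosis genes did (median -0.38, adjusted p = 0.00318 and 0.8957). With hairpin 3, H2AJ differed by 0.40 ± 0.79 (n = 5 each), CXCL8 by 1.59 ± 1.29, IL1A by 1.03 ± 0.81, IFI27 by 1.37 ± 0.89 and CDC20 by -1.20 ± 1.39. For hairpin 3, 37 of 37 interferon-stimulated genes (median 0.53) and 24 of 25 p53 targets (median 0.16) had a positive difference (adjusted p = 5.78e-09 and 6.96e-05 with the preset correlation, 0.5795 for both with an estimated one). All 36 mitosis genes (median -0.54) and 29 of 31 DNA replication genes (median -0.45) had a negative one (adjusted p = 2.58e-05 and 0.0001 with the preset correlation, 0.5795 for both with an estimated one). With the preset correlation 5 lists passed with hairpin 2 and 10 with hairpin 3, and with an estimated correlation 0 passed in either. The preset counts changed widely when single arrays were left out, as given below. In control senescence all 36 mitosis genes had a positive difference, and whether the controls differ from hairpin 3 cells in this was not tested. With complemented hairpin 2, H2AJ differed by 0.89 ± 0.79 (n = 5 each), IL6 by -0.27 ± 0.78, MMP1 by -0.01 ± 0.47 and PRC1 by -0.17 ± 0.94, and no list of 21 passed. In each of these 0 of 13953 genes passed (limma, 187, 276 and 160 at an unadjusted p under 0.05 with hairpin 2, hairpin 3 and complemented hairpin 2). The limma adjusted p was at least 0.9991 for every gene named.

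Senescent controls of set 2 (n = 3) were compared with those of set 1 (n = 5), which carry the same hairpin per the labels, though H2AJ goes against the labels in both groups. Sterol synthesis genes gave the lowest adjusted p among the genes named, with HSD17B7 at -1.42 ± 0.40 (SE; limma adjusted p = 0.0657), MSMO1 at -1.22 ± 0.35 (0.0666), CYP51A1 at -0.95 ± 0.23 (0.0657) and IDI1 at -0.95 ± 0.28 (0.0691). Of 20 cholesterol synthesis genes 10 passed when adjusted over the list alone and 0 over all genes. The basement membrane collagen genes COL4A1 and COL4A2 differed by 1.07 ± 0.40 and 0.87 ± 0.29, the p53 target CCNG1 by -0.92 ± 0.29 (adjusted p = 0.0731), and 36 of 36 mitosis genes had a positive difference (median 1.24, CDC20 at 2.73 ± 1.60). H2AJ differed by -0.90 ± 0.92 and IL1B by 1.73 ± 0.83. Over all genes 0 of 13953 passed (limma), while 2997 had an unadjusted p under 0.05. With the preset correlation 6 lists passed, including cholesterol synthesis (adjusted p = 0.00724) and mitosis genes (adjusted p = 6.47e-05), and no list with an estimated correlation (adjusted p = 0.9724 for both). With array weights 6048 genes passed, where control 8 of set 2 had a weight of 0.413 against 3.474 and 2.314 for controls 7 and 9. When these 8 arrays were fitted alone, 1454 genes passed. All 5 arrays of set 1 stood among the first 23 arrays of the deposited table and all 3 of set 2 among the last 18, between which 514 genes had no overlap. With that position as a term 0 genes passed (limma) and 172 had an unadjusted p under 0.05.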

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

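The tests on single arrays covered TOP2A and GDF15, chosen after their values were seen, and the tests of explanations in this part were chosen after the result was seen.

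Of 120 combinations of a labelled group and a measure, 8 held a single array far from the others of its group. Chance gives about 6 for independent measures, but the 8 fell on replicates P, C, D and X, with more than 1 on each. TOP2A was the highest of the labelled group on each of these (1428.2, 2740.9, 468.1 and 1373.6), and their labels are in doubt, as given below. H2AJ was 259.7 on replicate P labelled hairpin 2 in senescence, against 1609.2 to 1768 on the others, and MKI67 was 141.4 on that array against 108.9 to 113.2 on the others, which were not above background for MKI67. H2AJ was 495.6 on replicate C labelled hairpin 3 in senescence, against 1661.4 to 2421.4 on the others, and the chemokine gene CCL2 was 669.7 there against 2179.7 to 3528.2. CDKN1A was 12545.5 on replicate D of the proliferating controls, against 25127.4 to 27407 on the others, and CCL2 was 1357.3 there against 4334.7 to 5226.3. IL6 was 1072.5 and CXCL8 was 305 on replicate X of the senescent controls of set 1, against 6483 to 12281.5 and 9286.2 to 23090.6 on the others.

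The interaction of hairpin 2 and labelled state passed for 9 lists with camera at the preset correlation. None passed with an estimated correlation (lowest adjusted p = 0.2718) or fry (0.4339). Negative were mitosis (preset adjusted p = 1.76e-05), DNA replication (0.000177), cholesterol synthesis (0.000214), fibroblast identity (0.000852) and extracellular matrix genes (0.00644). Positive were interferon-stimulated (6.38e-05), glycolysis and hypoxia (0.00604) and unfolded protein response genes (0.00644), and cytokines and chemokines (0.0445). The complementation difference passed for 5 lists at the preset correlation and for none with an estimated one (lowest adjusted p = 0.857) or fry (0.9441). Positive were growth factors and binding proteins (0.0146), cholesterol synthesis genes (0.0234) and p53 targets (0.0474). Negative were mitosis (0.0146) and DNA replication genes (0.0474). All of these are contrasts of labels, not shown to be differences between the cells the labels name.

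Arrays with the same label did not resemble one another: only 6 of 41 arrays had as their nearest array, by correlation over genes, one with the same label, where random labels gave 3.7 on average (permutation p = 0.225). Noise between arrays as the reason is argued against by the mitosis gene mean, which left a gap of 2.49 log2 units between 9 arrays at 7.28 to 7.40 and 9 arrays at 9.89 to 10.10 among the last 18, with 5 of the 10 arrays there labelled senescent in the lower part, while the largest gap among the first 23 was 0.86, within the bound of 1 that was set after the values were seen. A failure of the cells to change state is argued against by the span of that mean, 2.81 log2 units in the last 18 arrays and 1.59 in the first 23. The labels may be attached to the value columns in another order. On the first 23 columns, the labels of set 2 read in reverse order of the columns gave all 23 arrays a nearest array with the same label. There 10000 random orders gave at most 15 (permutation p = 1e-04, the smallest they can give, for the best of 4 orders tried). In that reverse order H2AJ lay at 165.5 to 336.8 on hairpin 3 arrays in proliferation, 1167 to 1609.2 in senescence, and 2843.1 to 3008.7 on senescent controls. TOP2A lay at 443.3 or above on arrays of proliferating cells and at 242.6 or below on those of senescent cells. These values go with the reverse order and argue against the labels as given on these columns, though both genes also entered the correlation. For the last 18 columns the best of the same 4 orders of the set 1 labels gave 3, so no order was found there. Arrays there with TOP2A at 2358 or above had H2AJ at 310.1 to 495.6 or at 1038.8 to 1524.9. Those with TOP2A at 218.3 or below had H2AJ at 1684.2 to 2061.5 or at 3142.8 to 3906.2. Both TOP2A levels occurred under every label given there, which argues against the labels as given on these columns too. The ranges go with the groups of set 1 in an order not tried, which was not tested further. No sample was moved to another group on this ground, and a difference in the biology of the labelled groups was not testable under these labels.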

How the results depend on the processing

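The position of an array as a term and the last 18 arrays alone were chosen after seeing the data; the other alternatives were planned. Of 136 fits under alternatives other than leaving out an array, 132 called 0 genes, as did all 125 fits without 1 array. Array weights called 1 gene for control senescence, 3127 for hairpin 3 in senescence (H2AJ 2.01, stronger than 0.94) and 6048 for senescent controls of set 2 against set 1, and only the arrays of the compared groups called 1454 for the last of these. These weights ran from 0.342 to 3.474, and were 3.474, 2.314 and 0.413 for senescent controls 7, 9 and 8 of set 2. TOP2A was 2892, 2968.9 and 203.1 on these arrays, so the weighted mean of this group rested mostly on controls 7 and 9. Of 3796 values of named genes under alternatives, 43 passed, all with the direction kept. The cause was not tested further.

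Leaving out 1 array at a time, the H2AJ difference ran from -0.79 to 0.04 in control senescence (turned without replicate X) and from -1.02 to 0.22 for hairpin 2 in senescence (turned without replicate P), from -1.85 to -0.91 for hairpin 2 in proliferation, 0.32 to 2.11 for hairpin 3 and 0.81 to 2.61 for complemented cells in senescence. The number of lists called ran from 0 (without senescent control X) to 11 in control senescence and from 0 to 8 (without senescent P) for hairpin 2 in senescence. It ran from 9 (without proliferating I) to 14 for hairpin 2 in proliferation, 7 to 13 for the interaction, 3 (without control 7) to 10 for hairpin 3, and 0 (without control 7 or 9) to 7 for complemented cells. For the complementation difference it ran from 0 (without control 7 or 9, or complemented 2, 3 or 5) to 9 (without control X), and for hairpin 3 against complemented cells from 1 to 8 (without hairpin 3 C, or complemented 2 or 3). It ran from 1 (without proliferating H or I) to 12 (without senescent P) for senescence with hairpin 2, 5 (without proliferating 1 or 5) to 11 with hairpin 3, 0 to 4 with complemented hairpin 2, and 3 (without control V, Y, 7 or 9) to 8 for the controls of both sets.

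Camera with estimated correlation called 0 lists in all 12 comparisons. Only the larger relative changes in the number of lists called are given here, and smaller ones are left out. For hairpin 2 in senescence the number was 4 with only the arrays of the compared groups and 1 with array weights. For hairpin 3 in senescence it was 4 at an adjusted p under 0.01 and 4 in the last 18 arrays. For complemented cells in senescence it was 3 with array position after 23 as a term and 1 in the last 18 arrays. For the complementation difference it was 8 with the stricter filter, 8 with array weights, 0 at an adjusted p under 0.01 and 2 with array position as a term. For hairpin 3 against complemented cells it was 2 with no filter, 3 with the stricter filter, 4 with only the compared arrays, 3 with each set fitted on its own, 6 with array weights, 2 with the mean of all probes, 3 with array position as a term and 4 in the last 18 arrays. It was 4 for senescence with hairpin 3 in the last 18 arrays and 3 for the controls of both sets at an adjusted p under 0.01. For senescence with complemented hairpin 2 it was 1 with only the compared arrays, 5 with array weights, 2 in the last 18 arrays and 1 with the replicate block.

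Replicate numbers 1 to 5 were shared by the complemented arrays labelled proliferating and senescent. Their deviations correlated at 0.91, 0.84, 0.22, -0.78 and -0.68, and not every array correlated best with its own number. Since the labels may stand at the wrong arrays, these values cannot show whether the numbers paired the samples. The replicate block called 0 genes. Not run were the alternatives that need the table not used here (background correction from it, and no background correction as its contrast), median scaling, which is void on arrays with equal medians, a block for the chip, which the tables do not name, and each H2AJ probe on its own, since there is 1. The normexp correction was applied to normalized values, and sets were fitted but not normalized on their own. Signal over background limits LMNB1, CCL3, IL1A, IL1B and CXCL1, which lay below it on some arrays, and MKI67, whose highest intensity was 208 against a background of up to 135.8. CDKN1A and CXCL8 are limited at the other end, since they reached 28720 and 28129 against a highest value of 29764.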

Other observations

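The tests of explanations in this part, the division of the arrays after the 23rd of the deposited table, and the choice of genes by their spread were made after the values were seen.

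Without use of the labels, many of the gene lists varied together from array to array. Among the last 18 arrays the mean of the 36 mitosis genes ran from 7.28 to 10.10 on the log2 scale (SD 1.36 over arrays, where 10000 random lists matched on mean expression had a median SD of 0.04) and that of 31 DNA replication genes from 7.72 to 9.63. Over the same arrays the means of 25 cytokine and chemokine genes ran from 7.78 to 9.39, of 25 lysosome genes from 9.61 to 10.50 and of 25 p53 targets from 8.69 to 9.49. Among the first 23 arrays the 37 interferon-stimulated genes varied most, from 8.25 to 10.65 (SD 0.82), while among the last 18 they ran from 8.86 to 9.43 (SD 0.17). The SD of the list mean lay above the 95th percentile of random lists for 16 of 21 lists in the first 23 arrays and for 13 in the last 18. Extracellular matrix genes did so in the first (SD 0.26) and not in the last (SD 0.09, percentile 73.7). The 12 senescence state markers, which hold genes known to rise and to fall, did not (percentiles 67.5 and 9.1), nor did the 5 epithelial markers (79.9 and 52.9) or the 5 endothelial markers (93.9 and 88.3), and the 7 leukocyte markers lay at percentiles 96 and 94.9.

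The genes with the widest spread over all 41 arrays were the natriuretic peptide gene NPPB (117 to 9444, SD 2.27 on the log2 scale), CDC20 (187 to 14185), and the neutrophil chemokine genes CXCL1 (124 to 7174), CXCL6 (114 to 3878) and CXCL8 (246 to 28129). Next came the stress-induced GDF15 (207 to 8005), ANGPTL4 (267 to 8309), CCL3L3 (109 to 2442), CCND2 (352 to 7616) and PAPPA (233 to 7875). The adhesion gene VCAM1 ran from 311 to 8518 and the acute phase gene SAA1 from 104 to 1939. The low ends of NPPB, CXCL1, CXCL6, CCL3L3 and SAA1 lay under the lowest background level of 129.2, so their ranges have no measured low end, and the high end of CXCL8 lay near the highest value of the table, 29764, so the order of these genes by spread is not exact.

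Other splits of the same arrays, drawn at random where there were over 100, gave as many called genes in 100 of 100 splits or 56 of 56, as any split does beside a count of 0, so these counts say nothing about chance. The highest count in another split was 2 for control senescence, 179 for hairpin 2 in senescence, 783 for hairpin 2 in proliferation, 6 for the interaction, 1371 for hairpin 3 in senescence, 1 for complemented cells, 0 for the complementation difference and 1 for hairpin 3 against complemented cells. It was 809, 2566 and 2128 for senescence with hairpin 2, hairpin 3 and complemented hairpin 2, and 1 for the controls of both sets. Few splits gave any call, at most 7 in a comparison and 1 each for hairpin 2 and hairpin 3 in senescence. Splits with far more calls than the labelled groups point to a structure of the samples, which was not tested further.

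A step lay between the 23rd and 24th array of the deposited table: 514 genes did not overlap between the arrays before and after it, against at most 22 at any other place with at least 3 arrays on each side. A random order of the arrays gives 9.9e-10% of genes with no overlap there. Between the 18th and 19th array, where the 2 labelled sets change, 0 genes were without overlap, which would argue against the sets only if the labels stood at the right arrays; with the labels of set 2 on the first 23 arrays the sets would change at the step. It may reflect 2 batches of 23 and 18 arrays, but the 514 genes are the observation itself and no separate test of that was run. The labels of set 2 in reverse order gave all 23 of the first arrays a nearest array with the same label, as given above. This argues that the sets change at the step. A batch and a difference between the cells of the 2 sets would then coincide and cannot be told apart.

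The 2997 genes at an unadjusted p under 0.05 between the senescent controls of the sets may come from that step. With a term for it 172 genes lay under that p, below the 698 expected by chance, as the other comparisons did without the term. Of the 172 genes 89 were among the 2997. The median absolute difference of the 2997 genes went from 0.47 (median SE 0.18) to 0.11 (median SE 0.17) on the log2 scale. All 5 controls of set 1 lay before the step and all 3 of set 2 after it, so a difference between the controls themselves was separable from the step only through the other groups. Since the labels of the controls and of those groups may stand at the wrong arrays, the counts do not show whether senescent controls differ.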
